A study of Mus musculus with 2 samples.

How the data were processed

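Expression was measured on 2 Affymetrix mouse arrays, 1 for each of 2 stably transfected clones of LM8, a mouse osteosarcoma cell line that metastasises to the lung. One clone carried a full-length human PHD4 (hPHD4) cDNA in the pcDNA3.1 vector, and the other carried the empty vector. Both were selected with 0.5 mg/ml G418, and biotin-labelled targets were made from 5 µg of total RNA, per the labels' protocols. The deposited values are log2 signals per probe set, made with MAS5 per the submitters' processing notes; the MAS5 version and settings are not given in the sources used here. The log base and the scaling were settled from the values. Taken as powers of 2, the signals had a mean of 499.9 on both arrays after the highest and lowest 2% were trimmed, which is a global scaling of each array to 1 target. A value of exactly 0 on the log2 scale, a linear signal of 1, was held by 21 probe sets in the hPHD4 clone and by 68 in the control clone. MAS5 detection calls were not used here, so a floor on the signal took their place.

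Each array held 22690 probe sets, of which 64 were control probe sets. The platform annotation gave 1 gene symbol to 20380 probe sets, several to 691 and none to 1555 non-control probe sets. Of those with 1 symbol, 20351 were found by gene number in a mouse gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names, chromosomes and the order of neighbouring genes; no coordinates are printed, because the annotation names no genome build. Probe sets with several symbols or none entered no gene value.

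No further scaling was applied. The floor of each array was the 40th percentile of its non-control probe sets, at a log2 signal of 6.34 (linear 81.1) in the hPHD4 clone and 6.08 (linear 67.8) in the control clone. A probe set counted as measured when it lay above the floor on both arrays. The value of a gene was the mean log2 ratio, hPHD4 clone over control clone, across its measured probe sets. A gene with no measured probe set, all of its probe sets under the floor on one array and its brightest above the 75th percentile on the other, was given as a bound: the bright signal over the higher of the floor and the dim signal. Measured genes at least 2-fold higher or lower were counted.

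With 1 array per group there is no replicate, no test and no p-value, and none of the differences has a replicate check. In place of replicate error, the SD of log2 ratios between probe sets of the same gene was pooled over 7007 probe sets of 2800 genes. It covers error of single probe sets and leaves out differences between cultures, clones, labelling reactions and arrays. The small number of arrays limits the precision.

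Gene lists were fixed before the data were examined. They covered oxygen sensing and HIF subunits, HIF target genes, glycolysis, EGF family ligands and receptors, pro-angiogenic and anti-angiogenic factors, extracellular matrix, proteases and inhibitors of invasion, integrins and adhesion, markers of 7 cell types, cell cycle and stress responses, signalling pathways, lipid synthesis, and large complexes found by symbol pattern. A list was described when at least 3 of its genes were measured. The median log2 ratio of each list was placed among 10000 random lists of the same size, matched on mean signal in 10 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. Chance alone would put 2 of 40 lists there if genes varied independently. Genes of a list can move together, and some lists share genes, so more lists could do so. Members at least 1.5-fold higher or lower were counted. These percentiles describe these 2 arrays and do not speak for clones in general. Chromosome medians were placed in the same way; they were planned for the closing observations and are also given in the report as measured values.

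The named genes followed a rule fixed before the data were examined. It took the 12 genes with the highest and the 12 with the lowest log2 ratio among those with 1 of the 2 signals above the 60th percentile and all measured probe sets of one sign, passing over symbols of clones and predicted genes. It also took up to 5 bounds in each direction, P4htm, Tgfa, Hif1a and Vegfa, and from each list described the 2 to 4 members that lay farthest in the direction of the list's median. List members that lay the opposite way were named after their values were seen.

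Alternatives to the scaling, floor, filter, choice of probe set and fold threshold were listed before the data were examined. Subtraction of the median of each gene's chromosome was added after seeing the data. In the alternative with no filter, dim signals were raised to a floor. A separate floor for each array was tried first and gave every gene dim on both arrays the same positive ratio, so 1 common floor, the higher of the 2, was chosen after seeing that. The loess correction was a local linear fit with tricube weights and a span of 0.3.

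The steps were tested on data simulated from the control array over 7702 genes. Of genes given a true log2 change of 1, 18 of 45 (40.0%) passed the 2-fold threshold. At a change of 1.5, 2 or 3, all were recovered (44, 42 and 35 genes), and 13 of 6539 genes with no change also passed. Every probe set was given noise of the same SD (0.35), whereas the spread in the data was 0.40 for dim and 0.28 for bright genes. The 13 genes therefore give no false rate for the data. Of 50 lists of 20 genes shifted by 0.3, 46 stood apart, as did 10 of 200 unshifted lists. In these simulations genes varied independently, so the share of unshifted lists standing apart was set by construction. It says nothing of real lists, whose genes can move together. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.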

Results

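The data were 2 arrays of LM8 mouse osteosarcoma cells, 1 from a clone stably expressing human PHD4 and 1 from a clone with the empty vector. PHD4, encoded by P4htm in the mouse, is a prolyl hydroxylase anchored in the endoplasmic reticulum membrane and related to the enzymes that mark hypoxia-inducible factor (HIF) alpha subunits for degradation. The comparison asked how the transcriptome of cells overexpressing human PHD4 differed from that of control cells. Median signals over all probe sets were 135 in the hPHD4 clone and 122 in the control clone on the linear scale. Of 12393 genes on the array, 7452 were measured above the floor in both clones. Log2 signals correlated between the clones with Pearson's r of 0.965 and Spearman's rho of 0.961 across these genes, which are not independent replicates.

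The transgene itself could not be followed. The array carries mouse probes, and 0 probe sets were assigned to P4htm alone, so the group labels were not checked against the gene that was introduced. Hif1a, the HIF-1 alpha subunit, had a log2 ratio of 0.17, with its 3 measured probe sets at −0.18, 0.19 and 0.52. Vegfa, the principal angiogenic growth factor among HIF targets, had a ratio of −0.07. For both genes the difference was smaller than the disagreement between probe sets of one gene at their brightness, an SD of 0.37. Tgfa, encoding the EGF receptor ligand TGF-alpha, was close to the floor. Its only probe set measured in both clones had a log2 ratio of 0.40 (1.32-fold higher in the hPHD4 clone, linear signals 137 and 104), against an SD of 0.40. Another probe set of Tgfa lay above the floor in the hPHD4 clone alone, at log2 signals of 6.71 and 4.99, and with the floor at the 20th percentile the ratio of the gene was 1.06.

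Ctsh had the highest ratio of all measured genes that met the naming rule. Ctsh and Ctsc, which encode the lysosomal cysteine proteases cathepsins H and C, were 13.7-fold and 6.02-fold higher in the hPHD4 clone. Gas6, a secreted ligand of the Axl, Tyro3 and Mertk receptors, was 10.1-fold higher, with linear signals of 2110 and 209.6. Pnpla2, encoding adipose triglyceride lipase, was 8.12-fold higher on 1 of its 2 probe sets. With the floor at the 20th percentile both were measured and its log2 ratio of 3.02 became 1.36. Htra1, a secreted serine protease, was 4.14-fold higher, with log2 ratios of 1.77 and 2.33 for its 2 probe sets, an SD of 0.40 against 0.28 for genes of its brightness. The carbonic anhydrase gene Car14 was 5.23-fold higher, and the LIM-domain gene Fhl1 5.16-fold higher. Gask1b, Cystm1, Zdhhc12 and Fgl1 were between 3.98-fold and 5.62-fold higher, but the control signals of Zdhhc12 (68.5), Fgl1 (76.1) and Gask1b (86.7) were close to the floor of 67.8. Mndal, at 4.17-fold, belongs to the interferon-inducible Ifi200 family of closely similar genes, and its value is uncertain for that reason.

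Genes of the small leucine-rich proteoglycans, which bind collagen fibrils, made up 5 of the 12 genes farthest below the control clone, a grouping made after the values were seen. Ogn (osteoglycin) was 11.1-fold lower in the hPHD4 clone, with log2 ratios of −3.84 and −3.11 on its 2 probe sets (SD 0.51 against 0.37 for genes of its brightness), both close to the floor in that clone. Lum (lumican) was 6.16-fold lower, Prelp 5.66-fold lower, Omd (osteomodulin) 4.43-fold lower and Dcn (decorin) 3.44-fold lower. Fmod (fibromodulin), of the same family, was 2.93-fold higher in the hPHD4 clone, with ratios above 0 on all 6 of its probe sets. Thbs2, encoding the matrix protein thrombospondin 2, was 5.95-fold lower, with linear signals of 582.5 and 3818. Mgp (matrix Gla protein) was 4.79-fold lower. Fcer1g, the gamma chain shared by several Fc receptors, was 9.17-fold lower, at a signal of 106.8 in the hPHD4 clone, where the floor was 81.1. Slpi, a secreted inhibitor of serine proteases, was 4.50-fold lower, and S100a4, a calcium-binding protein linked to metastasis, was 4.25-fold lower. Mylk (myosin light chain kinase) was 3.76-fold lower, although its 2 measured probe sets, at −2.43 and −1.39, had an SD of 0.74 against 0.37. Scamp5 was 3.49-fold lower.

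A further 3 genes were bright in 1 clone and under the floor in the other. Tgfbi, a TGF-beta-induced matrix protein, was at least 11.1-fold higher in the hPHD4 clone, where all 4 of its probe sets lay above the floor, and all 4 lay under it in the control clone. The neuropeptide gene Nts was at least 10.1-fold higher. Mmp13, encoding collagenase 3, was at least 9.07-fold lower in the hPHD4 clone, with linear signals of 22.3 and 735.6.

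**Figure D1:**
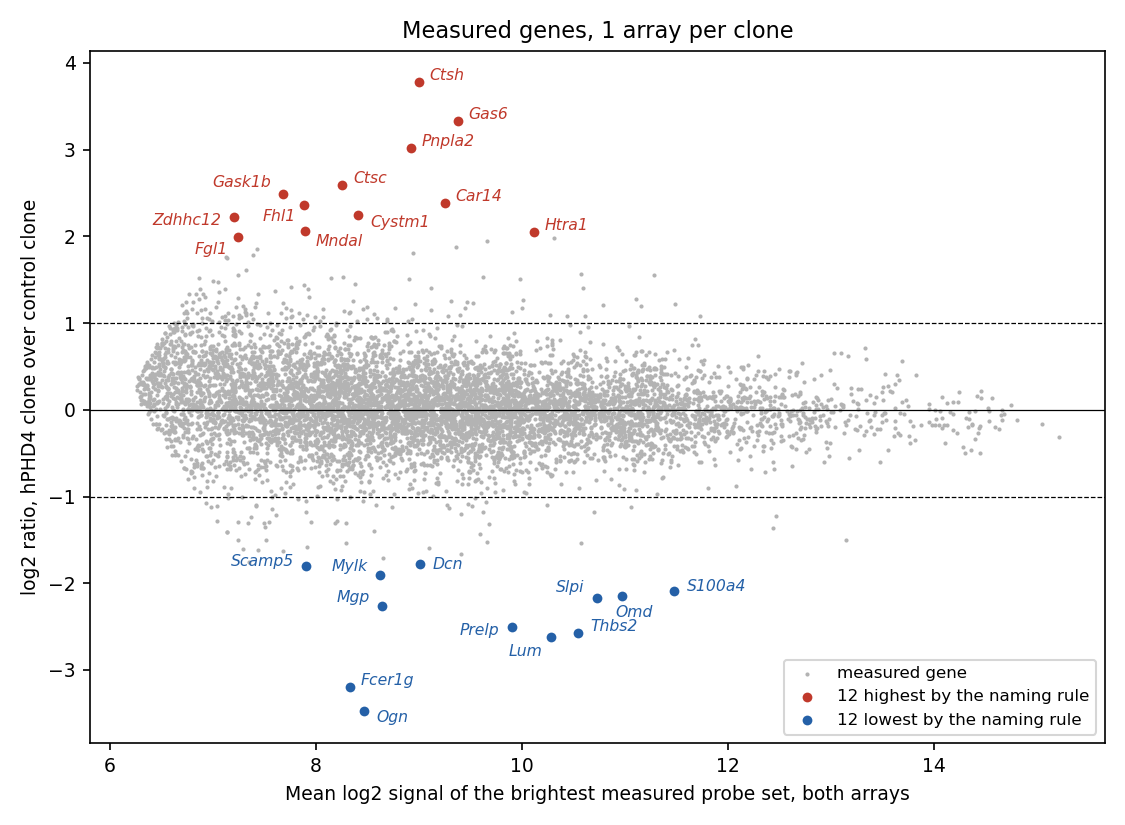
Log2 ratio (hPHD4 clone over control clone) of each of the 7452 measured genes against the mean log2 signal of its brightest measured probe set on the 2 arrays; dashed lines mark 2-fold differences, and the 12 highest and 12 lowest genes of the naming rule are coloured. Ratios of the named genes run from −3.48 for Ogn to 3.78 for Ctsh, and the grey cloud is widest among dim genes.

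Over all measured genes, 141 were at least 2-fold higher and 73 at least 2-fold lower in the hPHD4 clone, together 2.87%, while 85.8% lay within 1.5-fold. Of the 214 genes, 65.9% were higher; this share was 54.1% after quantile normalization, 52.4% after loess correction, 76.3% with the floor at the 20th percentile, 57.0% with it at the 60th and 52.5% at a 3-fold threshold. Only 21 of the higher and 9 of the lower genes had at least 2 measured probe sets, while 120 and 64 had 1. Of all 7452 measured genes, 2800 had at least 2. In all 21 and in 8 of the 9 the probe sets had the same sign. The 2-fold threshold on their mean makes opposite signs unlikely in any case, so this is no independent check. The spread between probe sets of one gene had an SD of 0.35, from 0.40 for the dimmest to 0.28 for the brightest of 3 groups of genes. The groups divide all measured genes equally by mean signal, so the genes behind the SD need not divide equally. Of the 24 genes at the extremes, 15 were no longer measured in both clones with the floor at the 60th percentile, Ctsh, Gas6 and Ogn among them.

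Of 40 gene lists with at least 3 measured members, 10 stood apart from matched random lists, 6 higher and 4 lower. If genes varied independently, 2 would do so by chance, and more where the genes of a list move together. Genes induced by interferon had the highest median. Among 16 measured members 15 had ratios above 0, 8 were at least 1.5-fold higher in the hPHD4 clone and 1 was at least 1.5-fold lower. The median log2 ratio was 0.56, above the central range of random lists (−0.16 to 0.30). Usp18, the protease that removes ISG15, had a ratio of 0.87, Oasl2 of 0.83 and Ifit1 of 0.77, while Ifit3 lay at −0.65. With the floor at the 60th percentile 7 members were left and the list no longer stood apart (0.27). Its median was 0.35 after loess correction and 0.23 with dim probe sets kept, and it stood apart in both.

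Lists of angiogenic regulators lay on opposite sides. The pro-angiogenic list had a median log2 ratio of 0.42 over 14 measured members (random lists −0.17 to 0.28), with 3 members at least 1.5-fold higher and 2 at least 1.5-fold lower. The growth factor genes Pdgfc and Pdgfa had ratios of 1.28 and 0.68, and Ccn2, encoding connective tissue growth factor, 1.10. In the opposite direction lay Ptn (pleiotrophin) at −1.63 and Angptl4 at −0.65, and Vegfa was near 0. Only 8 of the 14 members were above 0, and the mean was 0.16. The median was 0.24 after quantile normalization, 0.25 after loess correction and 0.27 after subtraction of chromosome medians, and still stood apart. This list no longer stood apart with the floor at the 60th percentile (0.19) or with dim probe sets kept (0.00). The anti-angiogenic list had a median of −0.46 over 10 measured members (random lists −0.23 to 0.21), with 4 at least 1.5-fold lower and 0 higher. These 4 were Thbs2 at −2.57, Serpinf1, encoding pigment epithelium-derived factor, at −0.90, the metalloprotease gene Adamts1 at −0.68 and the protease inhibitor gene Timp2 at −0.60. With the floor at the 20th percentile its median was −0.20 and inside the random range, and with dim probe sets kept it was −0.17 and outside.

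The extracellular matrix list had members on both sides, 14 below 0 and 8 above. Its median log2 ratio was −0.26 over 22 measured genes (random lists −0.15 to 0.17), with 7 at least 1.5-fold lower and 4 at least 1.5-fold higher. The median was −0.02 with dim probe sets kept and −0.39 with the brightest probe set per gene. It stood apart in both settings and under every other alternative. Next to Lum, Mgp and Dcn, the elastic fibre gene Fbln5 had a ratio of −1.61. On the other side stood Eln, encoding elastin, at 0.94, the collagen genes Col8a1 at 0.86, Col6a3 at 0.74 and Col4a1, of basement membranes, at 0.67. Col6a1 and Col6a3 encode chains of the same collagen type and lay at −1.28 and 0.74. The osteoblast list had a median of 0.22 over 10 measured members (random lists −0.23 to 0.21), but a mean of 0.00. Ibsp, encoding bone sialoprotein, was at 1.09 and Dlx5 at 0.30, while Omd lay at −2.15; 1 member was at least 1.5-fold higher and 1 lower. This list returned inside the random range under 6 of the alternatives, among them quantile normalization and the loess correction (both 0.17).

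Genes of the Wnt pathway had a median log2 ratio of 0.43 and a mean of 0.23 over 12 measured members (random lists −0.20 to 0.28), with 7 above 0, 2 at least 1.5-fold higher and 1 lower. Axin2, a feedback inhibitor induced by Wnt signalling, was at 1.05, Sfrp2 at 0.67 and Wnt4 at 0.56, while Dkk3 was at −0.85. The list no longer stood apart when each gene was read from its brightest probe set (0.17) or when dim probe sets were kept (0.00).

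The metabolic lists described next had small medians that lay outside the random range. In the glycolysis list 14 of 16 measured genes had ratios above 0, and the median was 0.22 (random lists −0.19 to 0.16); 1 gene, the phosphofructokinase gene Pfkp at 0.67, was at least 1.5-fold higher and 0 were lower. The mutase gene Pgam1 followed at 0.45 and the glucose transporter gene Slc2a1 at 0.38. The glycolysis list stood apart under every alternative. In the cholesterol synthesis list 14 of 16 genes were likewise above 0, with a median of 0.20 (random lists −0.19 to 0.16), 2 at least 1.5-fold higher and 0 lower. These were Pmvk and Dhcr7, both at 0.69, and the list no longer stood apart with the brightest probe set per gene (0.04), after quantile normalization (0.17) or with the floor at the 20th (0.15) or 60th percentile (0.14). Without probe sets ending in _x_at or _s_at its median was 0.35. The amino acid response list, genes of amino acid supply induced through ATF4, had a median of −0.21 over 18 members (random lists −0.17 to 0.17), with 15 below 0, 4 at least 1.5-fold lower and 1 higher. Psph, of serine synthesis, was at −0.92, Pck2 at −0.70 and the mitochondrial folate enzyme genes Shmt2 and Mthfd2 at −0.66 and −0.59, while Atf3 was at 0.74. The median of this list was −0.39 after subtraction of chromosome medians.

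The antigen presentation list had a median of −0.32 over 10 measured genes (random lists −0.24 to 0.27), with 3 at least 1.5-fold lower and 0 higher. Cd74, the invariant chain of MHC class II, was at −1.11, and the peptide transporter genes Tap1 and Tap2 were at −0.65 and −0.59. Tap1, Tap2 and Psmb9, at −0.48, lie on chromosome 17, where the median of all measured genes was −0.17. Once each gene's chromosome median was subtracted, the list's median was −0.15 and inside the random range. It also no longer stood apart with the brightest probe set per gene (−0.17), with the floor at the 60th percentile (−0.08) or with dim probe sets kept (0.00).

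**Figure D2:**
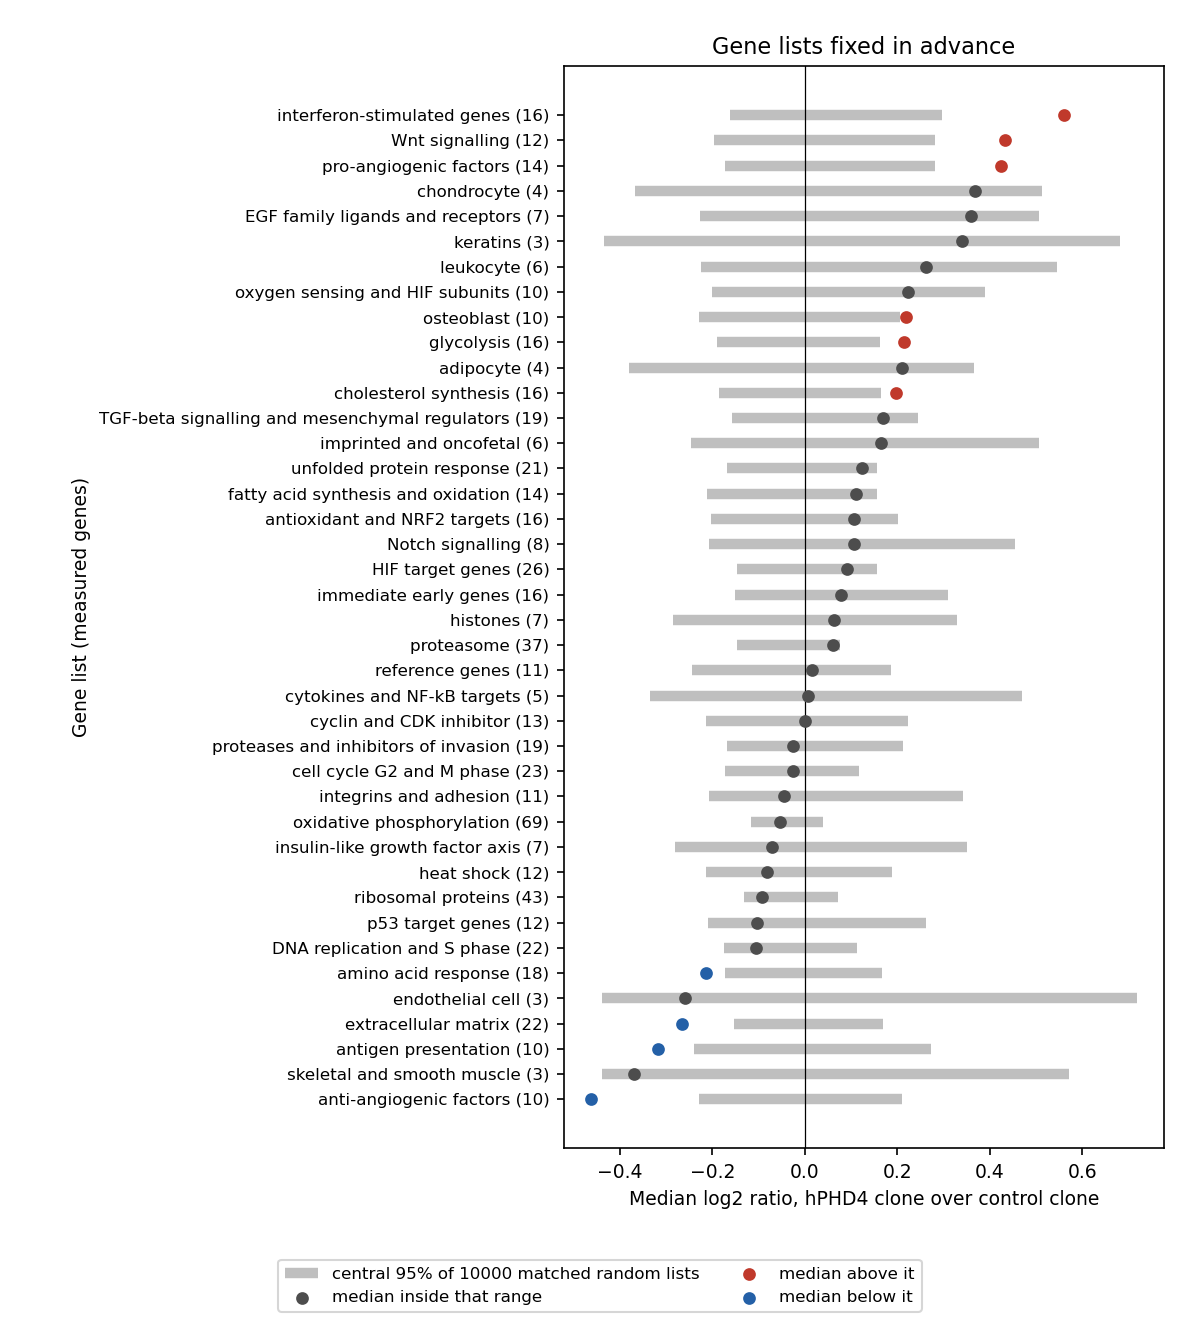
Median log2 ratio (hPHD4 clone over control clone) of each of the 40 gene lists, shown as a point with the number of measured genes in brackets; grey bars are the central 95% of 10000 random lists matched on signal. The 6 red points lie above their bars, led by interferon-stimulated genes at 0.56, and the 4 blue points below, led by anti-angiogenic factors at −0.46.

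Lists of the oxygen response did not stand apart, although the glycolysis list, which did, shares genes such as Slc2a1 with the HIF target list. HIF target genes had a median of 0.09 over 26 measured members, at the 86.9th percentile of random lists, with 1 at least 1.5-fold higher (Tfrc, the transferrin receptor, 0.66) and 3 lower, among them P4ha2, of collagen prolyl hydroxylation, at −1.11. With the floor at the 60th percentile 24 members were left, and the median of 0.15 then stood apart; with it at the 20th percentile, the median over 28 members was −0.03, inside the random range. The oxygen sensing list had a median of 0.22 over 10 members, with Epas1, encoding HIF-2 alpha, at 1.14 and the prolyl hydroxylase gene Egln2 at 0.57; the signal of Epas1 in the control clone was close to the floor. The EGF family list had a median of 0.36 over 7 members, with Erbb3 at 0.64 and Hbegf at −0.53.

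The lists of TGF-beta signalling (median 0.17), unfolded protein response (0.12) and proteasome (0.06) lay inside the random range as well. Tgfbi of the first list, at least 11.1-fold higher in the hPHD4 clone, was given only as a bound and does not enter its median. In the first list 13 of 19 members were above 0, 4 at least 1.5-fold higher and 1 lower. Its members Tgfb2, Ccn2 and Id2 had ratios of 1.55, 1.10 and 1.03, while the mesenchymal transcription factor genes Zeb2, Twist1 and Twist2 were at −0.62, −0.58 and −0.57. The median of this list stood apart after quantile normalization or loess correction (both 0.23) and with the floor at the 60th percentile (0.25). Xbp1 and Atf3 of the second had ratios of 1.21 and 0.74, and with the brightest probe set per gene that list (0.17) and the proteasome list (0.08) stood apart. For proliferation, the G2 and M phase list had a median of −0.03 over 23 members and the S phase list −0.10 over 22. The cyclin and CDK inhibitor list was at 0.00 and the p53 target list at −0.10, both with Cdkn1a, the CDK inhibitor p21, at −0.97. Medians of the remaining functional lists were −0.03 for invasion proteases and inhibitors, −0.04 for integrins and adhesion, 0.11 for Notch signalling, 0.08 for immediate early genes and 0.01 for cytokines and NF-kB targets. Mmp13 of the invasion list, at least 9.07-fold lower, was likewise only a bound and does not enter its median. Further medians were 0.11 for fatty acid metabolism, 0.11 for antioxidant genes, −0.08 for heat shock, 0.17 for imprinted and oncofetal genes and −0.07 for the insulin-like growth factor axis. Ribosomal proteins lay at −0.09, oxidative phosphorylation at −0.05, histones at 0.06, keratins at 0.34 and reference genes at 0.02. Of the 30 lists that did not stand apart, 15 had a median of the opposite sign under at least 1 alternative.

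Few markers of other cell types were measured, and none of those lists stood apart. Leukocyte markers had a median of 0.26 over 6 members, of which Fcer1g lay at −3.20 and the other 5 between 0.00 and 0.48. The median was 0.37 for chondrocyte markers over 4 members, with Col9a1 at 1.16 and Col2a1 at 0.57, and that list stood apart with the floor at the 60th percentile, on 3 members (0.57). Adipocyte markers had a median of 0.21 over 4 members, muscle markers −0.37 over 3, with Acta2 (smooth muscle actin) 2.82-fold lower, and endothelial markers −0.26 over 3. Of the 13 epithelial markers, all on the array, 0 were measured in both clones.

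Measured genes differed by chromosome. The median log2 ratio was 0.31 on chromosome 19, 0.19 on chromosome 7, 0.16 on chromosome 1, 0.14 on chromosome 14, 0.11 on chromosome 2 and 0.07 on chromosome 11. It was −0.19 on chromosome 5, −0.17 on chromosome 17, −0.11 on chromosome 15, −0.07 on chromosome 4, −0.05 on chromosome 18 and −0.03 on chromosome 16. These 12 of 20 chromosomes stood apart from random gene sets, where 1 would by chance if genes varied independently. Those of chromosomes 11, 14, 16 and 18 returned inside the random range under at least 1 further alternative besides the one that kept dim probe sets. With the floor at the 20th percentile the medians of chromosomes 16 and 18 were positive, though still below the middle of random sets.

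**Figure D3:**
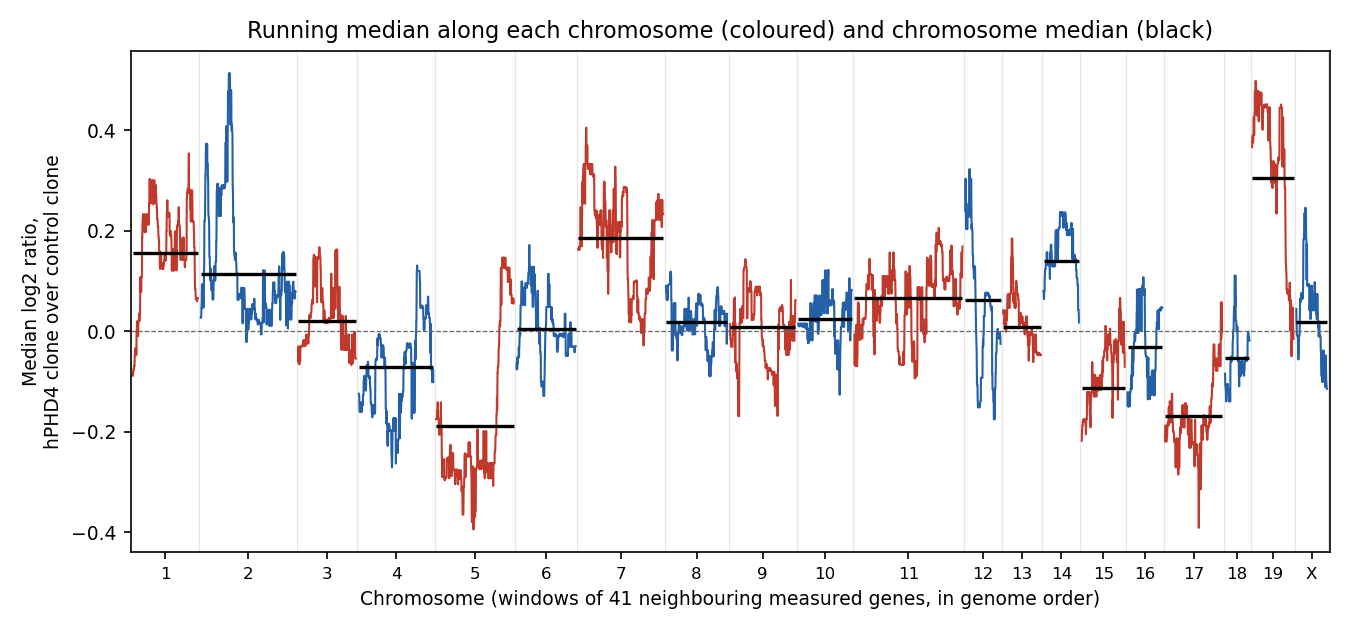
Running median of the log2 ratio (hPHD4 clone over control clone) in windows of 41 neighbouring measured genes along each chromosome (coloured lines), with each chromosome's median in black; the colours only separate neighbouring chromosomes. Windows reach 0.51 on chromosome 2, 0.50 on chromosome 19 and −0.39 on chromosomes 5 and 17.

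The control probe sets gave signs of RNA quality and hybridization. The ratio of 3′ to 5′ signal was 1.86 for Actb and 0.978 for Gapdh in the hPHD4 clone, and 1.58 and 0.911 in the control clone. The spiked hybridization controls were dimmer in the hPHD4 clone in 17 of 18 probe sets, with a median log2 difference of −0.39. Several of these probe sets read the same spiked transcript, so they are not independent measurements.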

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

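Probe sets that name no single gene entered none of the comparisons, and some of them differed between the clones. Of 961 such probe sets measured on both arrays, 27 were at least 2-fold higher in the hPHD4 clone and 9 at least 2-fold lower, together 3.75%. Their log2 ratios ran from −1.64 to 3.02.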

How the results depend on the processing

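The subtraction of chromosome medians and the common floor of the unfiltered setting were chosen after seeing the data. Of 540 values of summary results under an alternative, 481 stayed on their side of the limit (counts and the spread within 1.5 times). Of the 186 alternative values for lists and chromosomes that stood apart, 42 returned inside the random range and 0 stood apart in the opposite direction. Subtraction of the overall median shifts every ratio equally, so it cannot move a list or chromosome across its limit. Its values are counted here but could not have changed side. Where a list or chromosome did not stand apart its direction is not settled: 46 of 327 such values lay on the other side of the middle of random sets. The counts moved with the floor, for a cause that was not tested: genes at least 2-fold higher and lower numbered 605 and 188 with the floor at the 20th percentile and 45 and 34 with it at the 60th. At 3-fold they were 21 and 19 and at 1.5-fold 666 and 389, by construction. Genes bright on 1 array only numbered 1 and 16 at the lower and higher floor.

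With dim probe sets kept, members at the common floor have a ratio of 0 and fill the lists, so the medians of the pro-angiogenic, osteoblast, antigen presentation and Wnt lists, and of 11 of the 12 chromosomes that stood apart (all except 19), became 0. For the other changes that follow the cause was not tested. With the floor at the 60th percentile the median was 0.19 for pro-angiogenic, 0.14 for osteoblast, 0.27 for interferon-stimulated, −0.081 for antigen presentation and 0.14 for cholesterol genes, all then inside the random range, while HIF targets (0.15), chondrocyte (0.57) and TGF-beta genes (0.25) moved outside it. Chromosomes 11 (0.026), 16 (−0.0528) and 18 (−0.0529) moved inside. With the floor at the 20th percentile, anti-angiogenic (−0.20), osteoblast (0.22) and cholesterol genes (0.15) and chromosomes 11 (0.094), 14 (0.15) and 16 (0.041, above 0 but below the middle of random sets) moved inside, and chromosome 18 (0.0012) was above 0 but still stood apart as lower. Quantile normalization did so for osteoblast (0.17), cholesterol (0.17) and chromosome 16 (−0.0503), and loess for osteoblast (0.17) and chromosome 16 (−0.0509); TGF-beta genes moved outside under both (0.23 and 0.23). With the brightest probe set per gene, antigen presentation (−0.17), Wnt (0.17), cholesterol (0.041) and chromosome 18 (−0.028) moved inside, and unfolded protein response (0.17) and proteasome (0.084) outside. Without probe sets ending in _x_at or _s_at, osteoblast (0.22) and chromosomes 11 (0.0632) and 16 (−0.0056) moved inside. Subtracting chromosome medians did so for antigen presentation (−0.15).

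Of the 24 genes at the extremes, 15 lost their value with the floor at the 60th percentile, and 9 of these (Ctsh, Gas6, Pnpla2, Ctsc, Cystm1, Ogn, Fcer1g, Mgp and Mylk) joined the genes bright on 1 array only; Tgfa also lost its value. So did Zdhhc12 after loess correction, and Car14 and Mndal without probe sets ending in _x_at or _s_at. Of the 224 values of named genes left, 215 moved by less than the spread between probe sets of one gene. The others were Pnpla2 (1.36 with the lower floor, 1.51 unfiltered), Mndal (1.55 unfiltered), Htra1 (1.77 with the brightest probe set and without _s_at), Mylk (−1.27 unfiltered, −2.43 brightest), Scamp5 (−2.47) and Tgfa (1.06) with the lower floor. Many of the 215 could not have moved far. Most named genes had 1 measured probe set, which the choice of the brightest cannot change, and median subtraction moved every gene by 0.031.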

Other observations

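The families below, the scan for steps along chromosomes, the test against random placement of genes and the final reading of the density bins were chosen after the values were seen. Of 3 pairs of neighbouring small leucine-rich proteoglycan genes, 1 lay on opposite sides and 2 on the same side. Prelp had a log2 ratio of −2.50, while Fmod (fibromodulin), with 0 protein-coding genes between them on chromosome 1, was at 1.55 and higher in the hPHD4 clone on all 6 of its probe sets, from 1.18 to 1.81. The 2 neighbours Ogn and Omd on chromosome 13 were at −3.48 and −2.15, and the neighbours Lum and Dcn on chromosome 10 at −2.62 and −1.78. All 6 genes kept their sign after median subtraction, quantile normalization and loess correction. Probe sets of Bgn, Aspn, Kera, Epyc and Chad were at or under the floor on at least 1 array.

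Of 9 measured cathepsin genes, 3 were at least 2-fold apart, all higher in the hPHD4 clone: Ctsh at 3.78, Ctsc at 2.59 and Ctsk, the collagen-degrading cathepsin K of osteoclasts, at 1.08 (0.94 after quantile normalization and 0.95 after loess). The abundant lysosomal genes Ctsb, Ctsd and Ctsl were at −0.15, −0.03 and −0.53. Among 6 measured carbonic anhydrase genes, Car14 was at 2.39, Car3 at 1.88, Car11 at 0.74 and Car13 at 0.25, while the HIF target gene Car12 was at −0.22 and Car5b at −0.76. S100a4 at −2.09 was the only 1 of 6 measured S100 genes at least 2-fold apart; on the same chromosome S100a1 was at 0.85, S100a16 at 0.62 and S100a6 at 0.05. These signs held under the 3 other scalings.

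The first pattern weighed was the number of genes at least 2-fold apart, 214. Error of single probe sets alone was simulated 1000 times from the disagreement between probe sets of one gene. It gave at most 85 such genes, with a middle value of 58, which argues against it as the whole cause. The simulations hold no error between cultures, labelling reactions or arrays, and their residuals come from the 2800 genes with at least 2 probe sets. Whether hPHD4 or any other difference between 2 selected clones lies behind these genes cannot be told apart with 1 empty-vector array, because at least 2 control clones would be needed. An effect of hPHD4 therefore stays open and untested.

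The second pattern was the difference between chromosome medians. The SD of the 20 chromosome medians was 0.119, against at most 0.0416 in 10000 random placements of genes. This argues against chance placement, but it restates the comparison with random gene sets that defined the pattern and takes genes as independent. A bias that depends on brightness was tested by loess correction, which left an SD of 0.113. Gene density was tested within 4 bins of local density, where chromosome 19 lay above chromosome 5 by 0.27 (95% bootstrap interval 0.14 to 0.44), 0.54 (0.39 to 0.74), 0.45 (0.30 to 0.56) and 0.44 (0.17 to 0.56), against 0.49 over all genes. In 2 bins the interval reaches below the bound set beforehand. In the other 2 it lies above 50% of the difference over all genes (0.25). For these 2 chromosomes this argues against density as the whole cause in those bins, and the other chromosomes were not tested. Chromosomes 19 and 5 had the highest and lowest medians of all. Neighbouring genes shared shifts, so the intervals may be too narrow. A difference in gene dosage between the clones may underlie the shifts: both quartiles moved with the median on 8 of the 12 chromosomes, short of the share set beforehand, so it stays open without a measurement of DNA.

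The shifts were not even along chromosomes. In a scan for the best single step along each chromosome, 7 of 20 had a larger step than any of 1000 shuffles of their gene order. On chromosome 5 the first 384 measured genes had a median of −0.26 and the last 108 of 0.10. On chromosome 19 the first 209 had a median of 0.40 and the last 72 of 0.00, and on chromosome 12 the first 75 had 0.24 and the last 171 −0.03. After chromosome medians were removed, Spearman's rho between adjacent measured genes was 0.058 (100 shuffles, −0.023 to 0.024), still 0.051 at a distance of 20 genes and 0.016 at 50.

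The third pattern was the set of 10 gene lists that stood apart. Of these, 9 still did after chromosome medians were subtracted, which argues against chromosome-wide shifts as the whole cause. Shifts of parts of chromosomes were not tested for the lists. After loess correction 9 also still did. The random lists were already matched on signal, so the loess result could hardly differ and does not decide on brightness-dependent bias. The list lost was antigen presentation in the first case and osteoblast in the second. A difference between any pair of clones stays open for these lists as for single genes, and no biological explanation could be tested with 1 array per clone.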
